A study of Danio rerio with 4 samples.

How the data were processed

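The series holds 4 single-cell libraries made with 10x Genomics chemistry from intestines dissected from zebrafish larvae, 1 each for control and metronidazole at 4 and 5 dpf. Per the labels, intestines were dissociated with TrypLE and DNase, filtered, and sorted for live cells by exclusion of DAPI. The genotype label names the AB strain and no transgene. The feature list nevertheless holds an added entry called NfsB-EGFP. The deposited files hold raw UMI counts per gene and barcode for filtered barcodes, made with Cell Ranger 3.0 and the GRCz11 genome per the submitters' processing notes. Every value was a whole number, as raw counts are, and the 4 libraries shared 25433 features. Of their symbols, 1167 stand for several gene identifiers, which were kept apart. Chromosome positions were not used here. The titles of both 4 dpf libraries read ablation 4dpf and those of the 5 dpf libraries name the day without an ablation. The day in each title was taken as the day of the sample, and the labels give no time of treatment.

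Cells were kept with at least 500 UMIs, at least 250 genes and at most 25% of UMIs from the 13 mitochondrial genes. Scrublet, run on each library alone, called 37, 3, 126 and 0 doublets in control 4 dpf, metronidazole 4 dpf, control 5 dpf and metronidazole 5 dpf, and called cells were removed. In the last library its automatic threshold of 0.598 called no cell, although 92 cells scored over 0.25, so a limit of 0.25 in every library was added as an alternative. Of 30190 barcodes 23801 cells were kept; the UMIs per library and the median per cell stand with the results. The 4 libraries were clustered together without integration, after scaling to 10000 counts and a log transform, on 2000 variable genes, 30 principal components and 15 neighbours, with Leiden clustering at resolution 1.0 and seed 0. This gave 32 clusters, and the immune cells were clustered again on 15 principal components.

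Clusters were named from 295 marker genes of 22 classes, of which 11 were not in the feature list. The markers, gene lists, comparisons, filters and first set of alternatives were chosen before the data were examined. The rule that turns markers into names was set after the clusters had been seen. It asked for at least 3 markers raised, a mean log2 fold of at least 0.5, and either 1 marker among the 10 leading genes, 2 among the leading 20 or a mean log2 fold of at least 2. A cluster with exocrine leading genes (28, 0, 176 and 178 cells in the 4 libraries) and one of 8 control cells were left without a name, set by hand after they had been seen, because their leading genes went against the names goblet cell and macrophage that the rule gave. Cells without a name were 22.9%, 18.1%, 20.3% and 20.9% of the libraries. The names rest on transcripts alone.

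UMIs were summed over the cells of a class in each library and divided by that sum to give CPM values, computed here. Classes with at least 30 cells in both libraries were compared. Log2 ratios carry 1 CPM added to each side. Intervals are exact at 95%, Poisson for a CPM, Clopper-Pearson for a share, and the conditional binomial interval for a ratio of 2 counts without the added CPM. They cover counting error only and not the spread between larvae or preparations. Where a share was 0, its limit was taken as 3 counts of the total. Because each group held 1 library, no test between groups, no p-value and no count of changed genes over the whole genome is given, and cells were not treated as replicates.

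For each of 23 fixed lists (539 entries, 25 not in the feature list), members with at least 20 UMIs over both libraries were measured. A member counts as higher or lower when its ratio passed 1.5-fold and its counting interval excluded 1. The list's median log2 ratio was set beside the medians of 10000 random lists of equal size, matched on expression. These percentiles describe the libraries and are not p-values. The lists printed in a class are a part of those whose median lay outside the central 95% of random lists, chosen after their values were seen, and the insulin-like growth factor axis, the subject of the series. Lists whose value in a class came with another class's markers were left out.

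Genes were named by a rule. Among genes with at least 100 UMIs (all cells and enterocytes) or 30 UMIs (other classes) over both libraries, at least 20 CPM in one of them and a counting interval excluding 1, it took the 12 highest and 12 lowest log2 ratios in those larger sets and 5 each way in other classes. Genes under 5% of their level in another class were passed over as possible free RNA. From each list it took up to 4 extreme members. The genes printed are a part of those, chosen after their values were seen, as were NfsB-EGFP and the classes shown. Erythroid and myosin genes under 20 CPM in enterocytes at 5 dpf were added outside the rule. Each printed gene other than igfbp1a, igfbp1b and NfsB-EGFP had a counting interval that excluded no difference.

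Shares of cells with igfbp1a were also computed after thinning every cell to 1000 UMIs, which left out 17, 61, 12 and 133 enterocytes of control 4 dpf, control 5 dpf, metronidazole 4 dpf and metronidazole 5 dpf. Cycling cells were counted over 10 genes after the same thinning, which left out 123, 32, 337 and 390 cells in the order of libraries given above. Free RNA was not subtracted, as the deposited barcodes hold no empty droplets.

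The counting step was tested on simulated data with known folds in enterocyte-sized libraries. At 4 dpf the intervals held the true value for 97.98% of 99 genes set 2-fold apart and for 96.94% of 98 genes set 4-fold apart. The direction was right and clear for 98.99% and 100% of them. At 5 dpf the intervals held for 96% of 100 and 94.85% of 97 such genes, and between the control libraries for 92.78% of 97 and 94.74% of 95. Among unchanged genes 0% passed 2-fold with a clear interval, and 1, 3 and 0 of 20 unchanged lists lay outside the central 95% of random lists in the 3 comparisons. Both simulated libraries were Poisson draws from a shared profile, which is the model behind the intervals. They held no spread between cells, larvae or preparations. The simulation therefore checks the computation and says nothing of how far real libraries differ.

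The alternatives fixed at the start were a mitochondrial limit of 10%, every deposited barcode, called doublets kept, Leiden resolutions of 0.5 and 2.0, 15 principal components, median-ratio scaling, liver, acinar, erythroid and mitochondrial genes out of the total, means of per-cell CPM, a lower UMI minimum for genes, 10 CPM added in place of 1, a minimum of 1000 UMIs per cell, and other rules for cycling cells. Those added after the data had been seen were the Scrublet limit of 0.25, shares without hepatocytes, acinar and epidermal cells, single clusters of both enterocyte classes, and macrophages without one immune cluster. Adding 10 CPM shrank many log2 ratios of genes under about 20 CPM by more than 1.5 times, which is said here once because both CPM values stand beside each ratio. Python 3.11.15 was used with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.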

Results

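Single-cell RNA was counted in dissected intestines of zebrafish larvae at 4 and 5 days post-fertilization (dpf), from control larvae and from larvae given metronidazole. Bacterial nitroreductase turns metronidazole into a toxic product, so cells carrying that enzyme can be killed with the drug. The series title describes a model of damage to the intestinal epithelium and asks about macrophages and igfbp1a, which encodes a secreted insulin-like growth factor binding protein, in mucosal healing. Each of the 4 groups held 1 library. There were therefore no replicates within a group, and no difference between groups was tested. A treatment effect shared by both days was not tested either. Every interval given covers counting error only.

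The deposited libraries held 6919 barcodes for control at 4 dpf, 1458 for metronidazole at 4 dpf, 11679 for control at 5 dpf and 10134 for metronidazole at 5 dpf. In the same order they held 80545419, 20018301, 101232888 and 94830905 unique molecular identifiers (UMIs). After filtering, 5400, 1073, 9454 and 7874 cells were kept, with medians of 8792.5, 10833, 5668.5 and 5165 UMIs per cell. The median mitochondrial share of the kept cells was higher with metronidazole on both days, 7.17% against 4.62% at 4 dpf and 5.13% against 3.04% at 5 dpf. The feature list carried an entry for a fusion of nitroreductase with green fluorescent protein, NfsB-EGFP, and its transcripts were counted in control and metronidazole libraries alike. In enterocytes it stood at 166 CPM (UMIs scaled to a common total per class and library) in control and 96.4 CPM with metronidazole at 4 dpf, and at 89.3 and 92.7 CPM at 5 dpf. In fibroblasts, smooth muscle, endothelial cells and hepatocytes it stayed at or under 11.4 CPM.

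Cell classes were named by likeness to fixed marker genes (enterocyte-like, goblet-like and so on) and are written without that ending for brevity. The lysosome-rich or ileal enterocytes are called lysosome-rich enterocytes for short, although cluster 16, with 1619 of their 4230 cells, led with the bile acid genes fabp6 and slc10a2 of the ileum and had 5 of 13 class markers raised. Enterocytes made up a larger share of the cells with metronidazole at 4 dpf, 29.9% (Clopper-Pearson 95% interval 27.2 to 32.8) against 16.8% (15.8 to 17.8). Fewer cells carried the name in some alternatives, with shares of 6.62% against 3.24% under a Scrublet score limit of 0.25, 9.48% against 4.51% with called doublets kept and 3.98% against 2.37% with every deposited barcode. At 5 dpf they made up 23.1% (22.2 to 24.1) with metronidazole and 25.1% (24.2 to 26.01) in control. That small difference at 5 dpf turned to 27.0% against 26.6% when hepatocytes, acinar and epidermal cells were left out of the total, and its log2 ratio of -0.12 became -1.65 with 15 principal components and -1.08 at Leiden resolution 2.0. Lysosome-rich enterocytes were 23.2% against 23.4% at 4 dpf, and 18.4% (17.5 to 19.2) against 13.4% (12.8 to 14.2) at 5 dpf. That last pair was 8.16% against 7.32% with a mitochondrial share of at most 10%, 14.4% against 8.74% with 15 principal components and 19.8% against 10.87% with every deposited barcode. Goblet cells were 4.95% against 3.31% at 5 dpf. Enteroendocrine cells numbered 32 of the metronidazole cells at 5 dpf (0.406%) and 205 of the control cells (2.17%), a log2 ratio of -2.42 that was -1.16 with 15 principal components. The class of T, NK and innate lymphoid cells numbered 10 against 109 (0.127% against 1.15%), while macrophages numbered 74 against 68. Fibroblasts were 2.197% against 5.78% at 5 dpf, and 7.08% against 8.74% at 4 dpf. With a mitochondrial share of at most 10% these shares were 5.57% against 9.67% and 13.96% against 14.5%, and at resolution 2.0 those at 5 dpf were 4.70% against 8.64%. Shares of liver and pancreas cells also differed: hepatocytes were 9.96% with metronidazole and 4.04% in control at 5 dpf, and acinar cells 3.23% and 0.423%. No enteroendocrine cell was found among the 1073 metronidazole cells at 4 dpf, which allows a share of up to 0.280%, and 6 were found in the control. With 15 principal components 1.21% of the metronidazole cells and 1.87% of the control cells at 4 dpf carried that name.

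**Figure D1:**
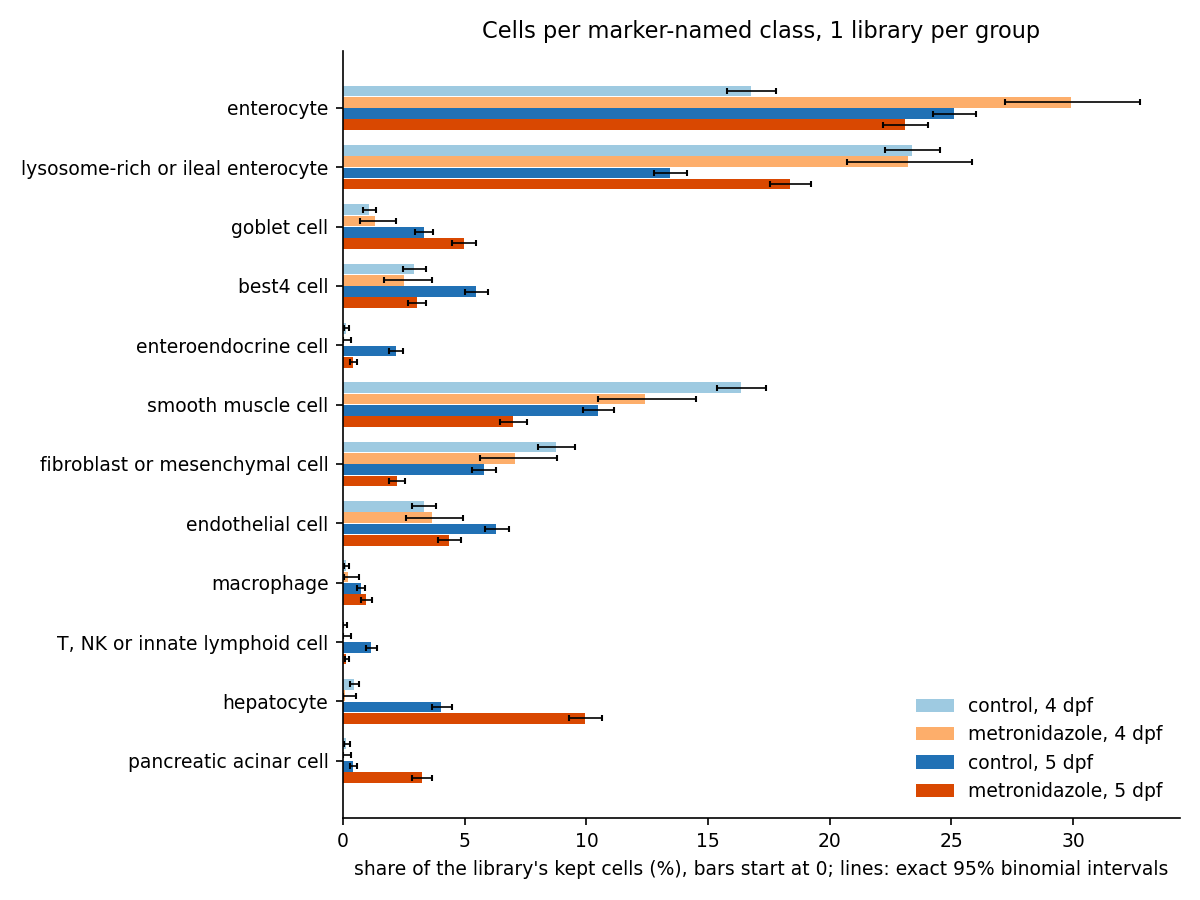
Share of kept cells (percent, horizontal axis) in each named class for the 4 libraries, 1 per group, with Clopper-Pearson 95% intervals for counting error. Enterocytes stood at 29.9% with metronidazole against 16.8% in control at 4 dpf, and hepatocytes at 9.96% against 4.04% at 5 dpf.

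The expression of igfbp1a (ENSDARG00000099351) was higher with metronidazole in both enterocyte classes on both days. In enterocytes at 4 dpf it stood at 309 CPM (exact Poisson 95% interval 298 to 320) with metronidazole and 18.2 CPM (16.7 to 19.8) in control, a ratio of 17.0 (15.5 to 18.7). At 5 dpf it stood at 96.8 CPM (92.8 to 100.8) against 30.8 CPM (29.1 to 32.6), a ratio of 3.14 (2.93 to 3.37), with 5.11 (4.41 to 5.93) in cluster 0, 2.37 (2.15 to 2.60) in cluster 1 and 4.22 (2.99 to 6.17) in cluster 2. Lysosome-rich enterocytes had more of it in control, 165 CPM at 4 dpf and 616 CPM at 5 dpf, and reached 870 and 1320 CPM with metronidazole, ratios of 5.28 (4.98 to 5.59) and 2.14 (2.06 to 2.23). At 5 dpf the ratio was 1.42 (1.26 to 1.60) in cluster 6, 1.503 (1.24 to 1.84) in cluster 7 and 2.21 (2.09 to 2.35) in cluster 16 of that class, and cluster 7 held 64.3% of its metronidazole cells against 3.15% of its control cells. Fibroblasts at 4 dpf stood at 2820 CPM (2679 to 2967) against 191 CPM, a ratio of 14.8 (13.4 to 16.2). These values rested on 76 metronidazole and 472 control cells, of which cluster 20 gave 15 and 165. At 5 dpf fibroblasts stood at 313 and 267 CPM, a ratio of 1.17 (1.01 to 1.36). The log2 ratio of that last difference, 0.23, turned to -0.29 with a mitochondrial share of at most 10%, -0.10 with every deposited barcode, -0.09 with called doublets kept and -0.23 at resolution 2.0.

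Among the other classes at 5 dpf, igfbp1a stood at 284 against 94.1 CPM in goblet cells, 80.6 against 25.1 CPM in best4 cells and 227 against 54.8 CPM in enteroendocrine cells. The ratio of 4.15 in enteroendocrine cells, a log2 ratio of 2.03, was 0.89 with 15 principal components. Endothelial cells held 607 against 411 CPM at 4 dpf and 436 against 378 CPM at 5 dpf, where the ratio was 1.02 (0.937 to 1.11) in cluster 5 and 1.93 (1.21 to 3.06) in cluster 30. The endothelial values at 4 dpf rested on 39 metronidazole and 179 control cells. Cluster 30 (89 control and 30 metronidazole cells at 5 dpf) had 10 of 13 endothelial markers raised but 0 among its 10 leading genes, which held 1 neutrophil marker, adam8a. Hepatocytes, the class with the most igfbp1a UMIs in the 5 dpf libraries, held 1107 against 1172 CPM, and their log2 ratio of -0.08 was 0.24 as a mean of per-cell CPM. Macrophages held 14.2 against 61.0 CPM at 5 dpf, and the log2 ratio of -2.03 was -0.03 as a mean of per-cell CPM. These values rested on 11 against 49 UMIs, and 48 of the 49 lay in a cluster of 9 control cells. In the macrophage cluster with the most cells (41 against 31) igfbp1a had 2 against 0 UMIs. Over all kept cells igfbp1a was 433 against 86.0 CPM at 4 dpf and 578 against 244 CPM at 5 dpf, with hepatocytes holding 73.6% and 64.3% of these UMIs at 5 dpf. The share of enterocytes with at least 1 UMI of igfbp1a was 57.6% against 14.6% at 4 dpf and 20.9% against 10.5% at 5 dpf. The corresponding shares in smooth muscle, taken as background, were 7.52% against 6.0% and 8.73% against 6.16%, and their median depths were 6344, 7172, 4630 and 4690 UMIs. Enterocyte median depths were 22544, 27553, 8809.5 and 10808 UMIs in the same order. With every cell thinned to 1000 UMIs the enterocyte shares were 23.0% against 1.35% and 6.76% against 2.55%, and those of smooth muscle 2.36% against 0.931% and 3.81% against 1.28%. Smooth muscle was thus not a fixed background, as its shares were higher with metronidazole on both days. Its igfbp1a ratios were 1.86 (1.15 to 2.91) at 4 dpf and 1.48 (1.17 to 1.86) at 5 dpf, under those of enterocytes. Control enterocytes, at 18.2 and 30.8 CPM, stood under smooth muscle with metronidazole on both days. The enterocyte ratios of 17.0 and 3.14 were therefore taken against a control level no higher than that background.

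**Figure D2:**
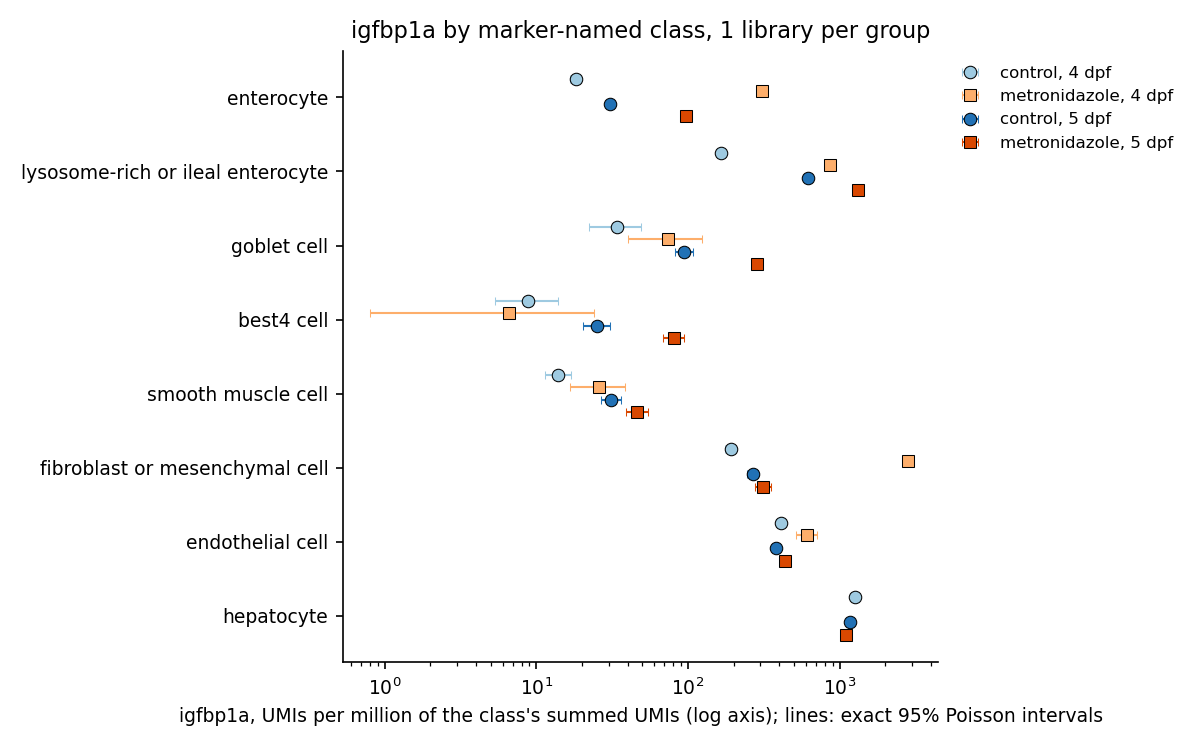
CPM of igfbp1a (log axis) by cell class in the 4 libraries, with exact Poisson 95% intervals. Enterocytes stood at 18.2 CPM in control and 309 CPM with metronidazole at 4 dpf, and at 30.8 and 96.8 CPM at 5 dpf.

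The enterocyte ratio of igfbp1a at 4 dpf moved in alternatives that kept another set of cells. Its log2 value of 4.01, with 1 CPM added to each side as in every log2 ratio of a gene given here, was 2.49 without cells of a Scrublet score above 0.25, 2.70 with called doublets kept and 2.88 with every deposited barcode. In lysosome-rich enterocytes at 4 dpf the value of 2.39 was 1.47 with 15 principal components, 3.42 with a mitochondrial share of at most 10% and 3.66 in cluster 16 alone. Cluster 16 held 836 against 65.2 CPM and cluster 6 held 930 against 339 CPM. Among enterocytes at 4 dpf, cluster 1 held 533 against 19.5 CPM and cluster 0 held 159 against 17.5 CPM.

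The comparison of metronidazole with control at 4 dpf asked how the larval gut differed at the earlier day. In enterocytes, single genes of glucose metabolism and lipoprotein handling were higher with metronidazole, while the lists of gluconeogenesis and fasting (4 of 18 higher, 1 lower, median 0.01) and of glycolysis and hypoxia (4 of 16 higher, 2 lower, median 0.07) lay within the random range. The gluconeogenic genes g6pca.1 (22.9 against 1.84 CPM, log2 ratio 3.07) and pck1 (2715 against 1006 CPM, 1.43) were higher, as was the glycolytic regulator pfkfb3 (161 against 42.2 CPM, 1.90). The apolipoproteins apoc1 (335 against 89.4 CPM, 1.89) and apoa4b.2 (ENSDARG00000094929, a symbol shared by several identifiers; 1108 against 296 CPM, 1.90) and the lipoprotein receptor scarb1 (454 against 152 CPM, 1.57) were higher as well. Cell cycle genes were lower: 23 of the 29 measured members of the list were at least 1.5-fold lower and 1 was higher, with a median log2 ratio of -1.13 where 95% of random lists lay between -0.25 and 0.10. The chromatin proteins of dividing cells hmgb2b (25.8 against 89.3 CPM, -1.76) and hmgn2 (49.7 against 168 CPM, -1.74) were also lower.

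Among the other genes higher in enterocytes at 4 dpf were the arginase arg2 (50.5 against 7.40 CPM, 2.62), the malic enzyme me1 (42.2 against 7.34 CPM, 2.38), cbsb (63.9 against 17.2 CPM, 1.83) and the peptidase anpepb (2704 against 979 CPM, 1.47). The solute carrier slc22a6l (3.40 against 23.5 CPM, -2.48) and the carbonic anhydrase ca4b (51.1 against 155 CPM, -1.58) were lower. In the cholesterol synthesis list 6 of 19 members were higher and 0 lower, with a median of 0.50 above all 10000 random lists. Its members hmgcs1 and sqlea stood at 330 against 249 CPM (0.40) and 13.1 against 6.87 CPM (0.84). At 5 dpf they stood at 230 against 48.5 CPM and 20.5 against 2.18 CPM. The 5 dpf metronidazole level was thus under the 4 dpf control level for hmgcs1 and above it for sqlea. The xenobiotic metabolism list had 6 of 17 members higher, among them cyp1a, which detoxifies aromatic compounds (355 against 194 CPM, 0.87), and a median of 0.51. Immediate early genes had 7 of 22 members higher and 1 lower (median 0.31), and the oxidative phosphorylation list had 2 of 20 higher (median 0.22). Smaller shifts stood in the lists of brush border transport and digestion (4 of 21 higher, 1 lower, median 0.17), lipid absorption (3 of 20 higher, median 0.14), and p53 targets and apoptosis (5 of 26 higher, 2 lower, median 0.15). Each of these medians lay above the central 95% of random lists. The insulin-like growth factor axis had 3 of 12 members higher, 1 lower and a median of 0.06, within a random range of -0.27 to 0.20. Enterocytes at 4 dpf had a median mitochondrial share of 10.5% with metronidazole and 5.61% in control. The oxidative phosphorylation list includes mitochondrial genes. Of the genes given here, only igfbp1a was also compared among enterocytes with a mitochondrial share under 5%.

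Enterocyte values at 4 dpf moved in alternatives that clustered another set of cells, where fewer cells carried the name. These were 71 metronidazole and 174 control cells with the Scrublet limit of 0.25, 102 and 245 with called doublets kept, and 58 and 164 with every barcode, against 321 and 906. In that order of alternatives hmgb2b was -0.65, -0.86 and -0.84, hmgn2 was -0.34, -0.79 and -0.51, and anpepb was 2.52, 2.55 and 2.18. In the same order hmgcs1 was 1.08, 1.12 and 1.16. The proliferation genes top2a (0.412 against 4.09 CPM, -1.85) and mki67 (1.24 against 9.48 CPM, -2.23) turned to 0.27, 0.34 and 0.31 and to 0.29, 0.18 and 0.90. With the Scrublet limit arg2 was 3.24 and sqlea 1.97, and with every barcode me1 was 3.72 and sqlea 2.05.

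In lysosome-rich enterocytes at 4 dpf, metronidazole went with higher elovl6, a fatty acid elongase (37.1 against 0.247 CPM, log2 ratio 4.93). The control value rested on 3 UMIs against 115, and the counting interval of the log2 ratio ran from 5.65 to 9.53 with no CPM added. Also higher were plek2 (22.0 against 1.81 CPM, 3.03), arg2 (48.4 against 6.60 CPM, 2.70), nab1b (74.3 against 11.13 CPM, 2.63) and the prostaglandin synthase ptgs2b (91.4 against 15.8 CPM, 2.46). The glycolytic regulator pfkfb3 (409 against 102 CPM, 1.99), the growth factor receptor egfra (634 against 344 CPM, 0.88) and cyp1a (270 against 92.5 CPM, 1.54) were higher too. Lower genes included vav3a (3.23 against 37.7 CPM, -3.19) and the transcription factor bcl11ab (13.2 against 56.1 CPM, -2.005). The xenobiotic list had 8 of 16 members higher and 1 lower (median 0.55), and the cholesterol synthesis list 9 of 19 higher (median 0.58), both above all random lists. Brush border genes (2 of 19 higher, median 0.35), the unfolded protein response (3 of 24 higher, median 0.19) and oxidative phosphorylation (0 of 20 past 1.5-fold, median 0.17) also lay above the random range. With 15 principal components elovl6 was 2.84, plek2 1.83, arg2 1.12, nab1b 1.08 and vav3a -4.36.

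In fibroblasts at 4 dpf, metronidazole went with higher metallothionein mt2 (200 against 12.3 CPM, log2 ratio 3.92), the cytokine il11a (64.2 against 5.53 CPM, 3.32), snap91a (336 against 37.2 CPM, 3.14) and the vasoactive peptide gene adma (92.6 against 10.2 CPM, 3.07). The angiogenic factor vegfaa (213 against 75.6 CPM, 1.48) was higher. The inflammatory list had 6 of 13 members higher and 1 lower (median 0.47), the heat shock list 7 of 16 higher (median 0.52), the glycolysis and hypoxia list 5 of 16 higher and 1 lower (median 0.41), and the unfolded protein response 3 of 22 higher (median 0.32). The insulin-like growth factor axis had 3 of 13 members higher and 2 lower (median 0.42). All 5 medians lay above the random range. The fibroblast values rested on 76 metronidazole and 472 control cells. Endothelial mt2, over 39 cells against 179, stood at 218 against 20.2 CPM, 3.37. With a mitochondrial share of at most 10%, mt2 in fibroblasts was 2.68, and adma was 1.89 at resolution 2.0.

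Over all cells at 4 dpf the median gene lay at -0.17. Against that, the immune metabolic gene irg1l (46.8 against 5.38 CPM, log2 ratio 2.91), slc26a3.1, an intestinal anion exchanger (22.1 against 2.81 CPM, 2.60), arg2 (57.6 against 13.6 CPM, 2.00), pfkfb3 (212 against 58.2 CPM, 1.85) and scarb1 (266 against 78.5 CPM, 1.75) were higher. The hormone gene ghrl, which encodes ghrelin, was lower (0.277 against 85.1 CPM, -6.08). So were the pancreatic trypsins prss1 (0.720 against 36.7 CPM, -4.45) and prss59.2 (0.166 against 40.4 CPM, -5.15), beside 0 acinar cells of 1073 against 7 of 5400 in control. For prss59.2 the metronidazole value rested on 3 UMIs, with a counting interval of -10.21 to -6.38 when no CPM was added. The cell cycle list had 15 of 30 members lower (median -0.65) and the acute phase and mucosal defence list 8 of 17 lower (median -0.53), both under all random lists and with 0 members higher. The insulin-like growth factor axis had 5 of 18 members lower and 3 higher (median -0.33, random range -0.27 to 0.10).

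The comparison at 5 dpf asked the same of the later day. In enterocytes, cholesterol synthesis stood out among the fixed lists. Of its 19 measured members 17 were higher with metronidazole and 0 lower. Their median log2 ratio of 1.27 lay above all random lists (range -0.02 to 0.22). From the start of the pathway to its end, hmgcs1 was 230 against 48.5 CPM (2.22), hmgcra 114 against 40.8 CPM (1.46), fdps 57.7 against 15.3 CPM (1.85), sqlea 20.5 against 2.18 CPM (2.76), lss 14.0 against 3.09 CPM (1.87) and cyp51 128 against 45.0 CPM (1.49). The later enzyme gene hsd17b7 (24.2 against 5.39 CPM, 1.98) was also higher. The low-density lipoprotein receptor ldlra stood at 280 against 157 CPM (0.82), and was 0.14 with 15 principal components. The interferon-inducible antiviral gene rsad2 (21.5 against 4.84 CPM, 1.95), pip5k1ca (44.0 against 11.4 CPM, 1.86) and the fatty acid binding protein fabp1b.2 (35.8 against 12.8 CPM, 1.42) were higher, and rsad2 was 2.55 with 15 principal components.

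Genes lower in enterocytes at 5 dpf included clca1 (ENSDARG00000016290, a symbol shared by several identifiers; 6.12 against 20.4 CPM, -1.59) and, with smaller differences, cox6a2 (128 against 209 CPM, -0.70), the chemokine ccl19b (19.2 against 31.5 CPM, -0.69), the glycerol channel aqp7 (24.4 against 37.5 CPM, -0.60) and the sterol exporter abcg8 (14.7 against 22.3 CPM, -0.57). Under the 20 CPM limit of the naming rule, the erythroid markers hbbe1.3, hbbe1.1 and hbae3 had 1, 0 and 0 UMIs with metronidazole against 567, 538 and 444. The myosin genes myl7, cmlc1 and myh6 had 293, 205 and 104 UMIs against 1, 0 and 2. No erythroid or heart class was named, so the free RNA filter had no such class to compare with. The unfolded protein response had 6 of 24 members higher (median 0.33) and the cell cycle list 4 of 25 higher (median 0.36, random range -0.05 to 0.19), with 0 lower in either. The insulin-like growth factor axis had 1 of 12 members higher, 1 lower and a median of 0.04 within the random range. The clusters behind the class differed between the libraries: cluster 2 held 62.8% of the metronidazole enterocytes and 7.12% of the control enterocytes at 5 dpf. In lysosome-rich enterocytes cluster 7 held 64.3% and 3.15%.

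In lysosome-rich enterocytes at 5 dpf, the lysosomal proteases ctsl.1 (16824 against 7786 CPM, log2 ratio 1.11) and ctsbb (1923 against 1055 CPM, 0.87) were higher with metronidazole, with 7 of 24 phagocytosis and lysosome genes higher and 3 lower (median 0.33). The ileal cluster 16 held 30.3% of the metronidazole cells of this class and 41.5% of its control cells. Cluster 6 held 5.39% and 55.4%, and cluster 7, with ctsl.1 and ctsbb among its leading genes, 64.3% and 3.15%. The class values cover that change of clusters as well. The glutathione-degrading enzyme gene ggt1a (21.5 against 1.04 CPM, 3.46), ptp4a3a (23.4 against 4.87 CPM, 2.06), tcima (66.7 against 19.3 CPM, 1.74), ptgs2b (35.15 against 14.1 CPM, 1.26) and pfkfb3 (426 against 186 CPM, 1.19) were higher. The inflammatory list had 6 of 11 members higher and 1 lower, with a median of 0.83 that was -0.05 as a mean of per-cell CPM. The unfolded protein response had 10 of 24 members higher (median 0.42), among them the stress transcription factor ddit3 (2029 against 1311 CPM, 0.63), and the cell cycle list 12 of 25 (median 0.58). The vitamin A binding protein gene rbp2a (426 against 1061 CPM, -1.31), the transcription factor gata5 (24.4 against 61.0 CPM, -1.29) and smad6b (7.97 against 21.2 CPM, -1.31) were lower.

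In the same cells lipid absorption had 10 of 20 members lower and 1 higher, with a median of -0.59 that turned to 0.29 with 15 principal components. Brush border transport and digestion had 6 of 20 lower and 0 higher (median -0.50), and both medians lay under all random lists. Both also cover the smaller share of the ileal cluster 16 in the metronidazole cells of this class. Further lists lay above the random range: repair and migration (5 of 19 higher, 2 lower, median 0.29, with egfra at 740 against 424 CPM), immediate early genes (5 of 23 higher, median 0.31), heat shock (2 of 12 higher, median 0.30), glycolysis and hypoxia (5 of 16 higher, median 0.27) and oxidative phosphorylation (0 of 20 past 1.5-fold, median 0.28). With 15 principal components rbp2a was -0.05, while ptp4a3a was 1.34. With a mitochondrial share of at most 10% ggt1a was 2.33.

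**Figure D3:**
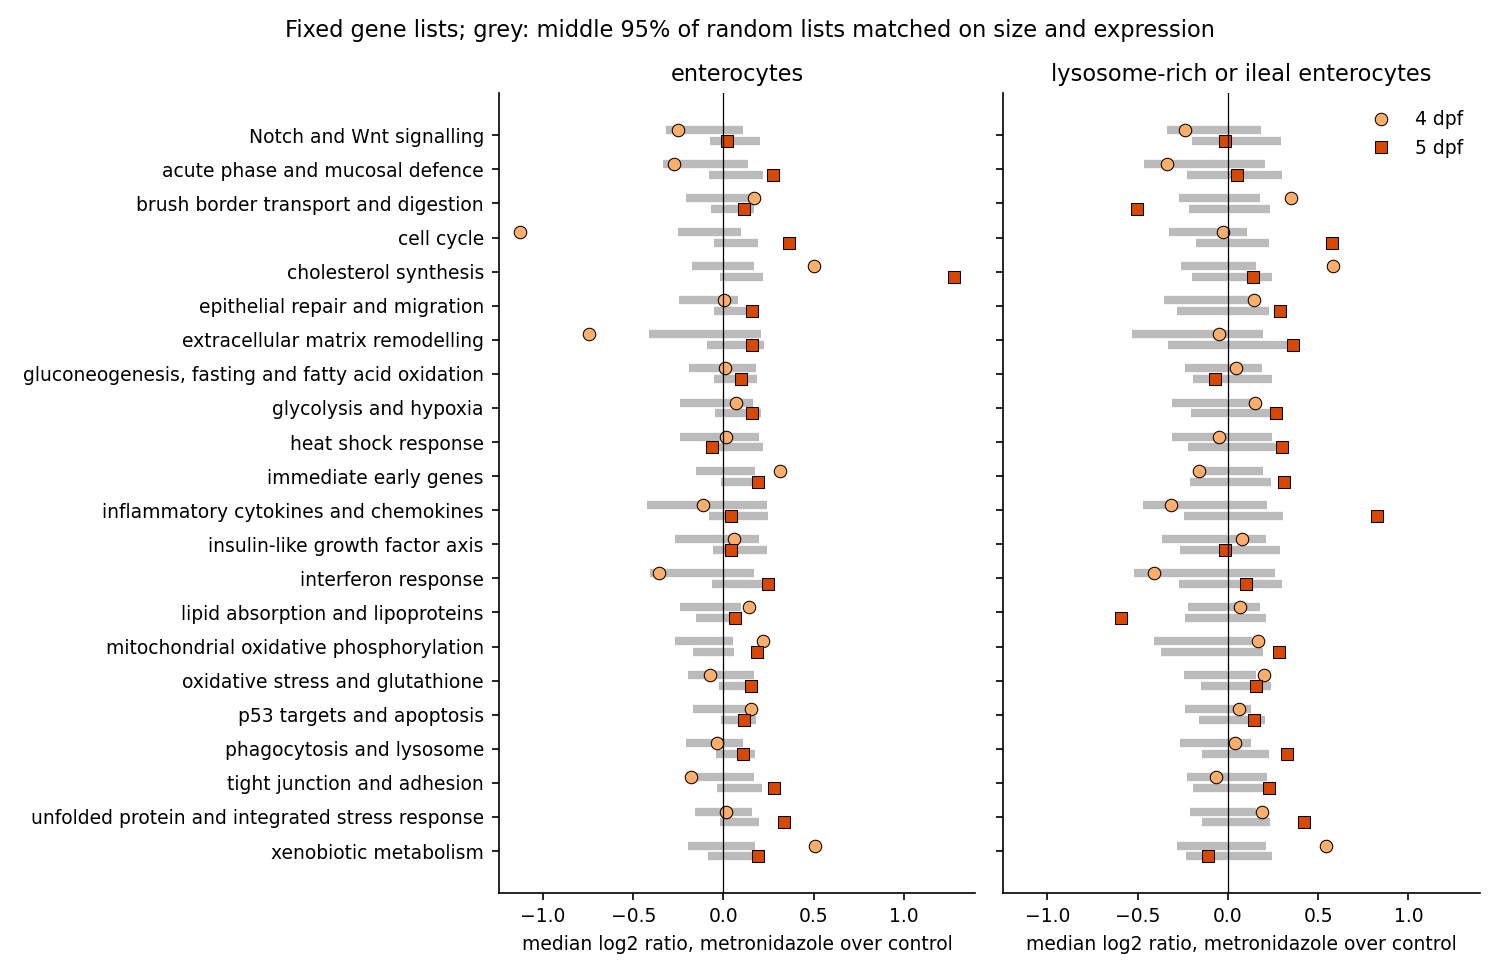
Median log2 ratio, metronidazole over control, of fixed gene lists in both enterocyte classes at 4 and 5 dpf, with the range holding 95% of 10000 matched random lists. The cholesterol synthesis median stood at 1.27 and the cell cycle median at 0.36 in enterocytes at 5 dpf, where the cell cycle median at 4 dpf was -1.13.

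In macrophages at 5 dpf, the lipoprotein gene apoeb (3722 against 1338 CPM, log2 ratio 1.48), the scavenger receptor marco (1093 against 453 CPM, 1.27), the complement genes c1qa (522 against 251 CPM, 1.05), c1qb (851 against 442 CPM, 0.94) and c1qc (1262 against 670 CPM, 0.91) and the growth factor receptor csf1ra (422 against 280 CPM, 0.59) were higher with metronidazole. Lower genes were the chemokines ccl35.2 (7.74 against 382 CPM, -5.45), cxcl11.5 (7.74 against 138 CPM, -3.99) and ccl19a.1 (1.29 against 82.2 CPM, -5.18), as well as grn1 (244 against 2020 CPM, -3.05) and arg2 (5.16 against 82.2 CPM, -3.75). For ccl19a.1 the metronidazole value rested on 1 UMI, with a counting interval of -11.32 to -3.47 when no CPM was added. The class included a cluster of 9 cells, all from the control library. Without it ccl35.2 was 0.60, arg2 1.25, ccl19a.1 -0.18 and grn1 -0.58, while cxcl11.5 was -4.34 (-2.76 as a mean of per-cell CPM). The higher genes then lay between 0.27 for csf1ra and 1.13 for apoeb. The values rested on 74 and 68 cells.

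Over all cells at 5 dpf, where the median gene lay at -0.32 and the enteroendocrine share was 0.406% with metronidazole against 2.17%, single hormone genes were lower. Somatostatin sst1.1 was 0.406 against 348 CPM (log2 ratio -7.96, or -6.46 as a mean of per-cell CPM), gip 0.274 against 79.8 CPM (-5.99) and ghrl 0.647 against 48.3 CPM (-4.90). The genes penka (24.5 against 400 CPM, -3.98), pyyb (44.7 against 427 CPM, -3.23) and gcgb (59.6 against 502 CPM, -3.05) were lower too, and penka was -3.13 as a mean of per-cell CPM. Within the 32 enteroendocrine cells of the metronidazole library sst1.1, gip and calca had 0 UMIs, against 33069, 7597 and 271 in the 205 control cells. The markers of that class do not set gut endocrine cells apart from those of pancreatic islets, where somatostatin is also made. The chemokines ccl38.6 (3.97 against 37.2 CPM, -2.94) and ccl20a.3 (4.32 against 40.1 CPM, -2.95) were lower over all cells. The pancreatic enzyme genes ela2 (1008 against 137 CPM, 2.87), ctrl (751 against 111 CPM, 2.75) and cpa5 (839 against 122 CPM, 2.77) were higher, beside the larger share of acinar cells. The cell cycle list over all cells had 17 of 30 members lower and 0 higher (median -0.71, random range -0.38 to -0.16). Lymphoid cells held 24868 of its 104116 UMIs in control and 2542 of 61403 with metronidazole, so this value covers the change in cell classes. Within classes its median was 0.36 in enterocytes, 0.58 in lysosome-rich enterocytes, 0.43 in smooth muscle, 0.25 in endothelial cells and 0.21 in fibroblasts. By summed CPM it was lower in hepatocytes, goblet cells, macrophages, enteroendocrine and epidermal cells.

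Hepatocytes at 5 dpf had higher hmox1a, which degrades heme (94.9 against 16.3 CPM, log2 ratio 2.47), odc1 (99.99 against 17.9 CPM, 2.42), klf9 (68.2 against 13.5 CPM, 2.25), hmgcra (54.7 against 12.2 CPM, 2.08) and fads2 (107 against 27.1 CPM, 1.94). Lower were tat, a tyrosine-degrading enzyme gene (65.9 against 459 CPM, -2.78), rbp5 (8.98 against 56.2 CPM, -2.52) and the iron exporter slc40a1 (4.76 against 29.8 CPM, -2.42). The cholesterol synthesis list had 8 of 19 members higher and 1 lower (median 0.52), and the cell cycle list 14 of 23 lower (median -0.66). In goblet cells slc4a4a, a bicarbonate transporter gene, was 557 against 168 CPM (1.72), tafa5a was 31.1 against 4.77 CPM (2.47, or 1.48 as a mean of per-cell CPM), and 7 of 13 heat shock genes were higher (median 0.62).

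The control libraries of both days, 1 for each day, were compared as well. Age cannot be told apart there from preparation or depth, with enterocyte medians of 27553 UMIs at 4 dpf and 10808 at 5 dpf. Control enterocytes, where the median gene lay at -0.31, had lower endoplasmic reticulum chaperone and cell cycle genes at 5 dpf than at 4 dpf. The unfolded protein response had 16 of 24 members lower (median -1.42), with manf at 4.58 against 74.7 CPM (log2 ratio -3.76), calr3b at 28.5 against 284 CPM (-3.27) and sdf2l1 at 3.01 against 31.3 CPM (-3.01). The cell cycle list had 26 of 29 lower and 1 higher (median -1.25). The redox genes gstp2 (47.8 against 409 CPM, -3.07) and prdx1 (44.1 against 331 CPM, -2.88) were lower, with 11 of 21 members of the oxidative stress list lower and 3 higher (median -0.62). Cholesterol synthesis had 12 of 19 lower (median -0.86), which was -0.07 with a mitochondrial share of at most 10% and -0.22 with the Scrublet limit. Higher at 5 dpf were diabloa (818 against 82.9 CPM, 3.29), epdl2 (980 against 126 CPM, 2.95), the uncoupling protein gene ucp1 (3785 against 825 CPM, 2.196) and ifi45 (54.8 against 11.9 CPM, 2.11). With a mitochondrial share of at most 10%, epdl2 was 2.00, ucp1 1.32 and manf -3.16. Interferon (5 of 10 higher, 1 lower, median 0.62), inflammatory (4 of 11 higher, median 0.37), brush border (5 of 21 higher, 2 lower, median 0.27) and p53 lists (6 of 26 higher, 3 lower, median 0.12 against a random median of -0.26) lay above the random range. The inflammatory median was 0.96 with the Scrublet limit, and gstp2 was -3.71 with called doublets kept and -2.43 at resolution 2.0.

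Control lysosome-rich enterocytes, with a median gene at -0.19, likewise had lower unfolded protein response (15 of 24 lower, 1 higher, median -1.38), cell cycle (25 of 29 lower, 1 higher, median -1.33) and cholesterol synthesis lists (12 of 19 lower, median -0.74) at 5 dpf. The interferon list had 4 of 9 members higher and 0 lower (median 0.51). The phosphatidate phosphatase lpin1 was 815 against 85.2 CPM (3.24), grn2 was 1.22 against 38.8 CPM (-4.17) and prdx1 was 13.6 against 134 CPM (-3.21). In cluster 16 alone grn2 was -2.98, prdx1 was -1.95 with 15 principal components, and lpin1 was 4.32 with a mitochondrial share of at most 10%. Control igfbp1a itself was 1.69 times (1.53 to 1.88) as high at 5 dpf in enterocytes and 3.74 times (3.53 to 3.95) in lysosome-rich enterocytes. Clusters differed: the ratio was 0.583 (0.495 to 0.687) in cluster 0, which held 60.9% and 56.9% of the control enterocytes, 3.90 (3.35 to 4.56) in cluster 1, 2.26 in cluster 6 and 8.01 in cluster 16. The log2 ratios of both classes, 0.73 and 1.90, were 1.74 and 3.15 with a mitochondrial share of at most 10%. In fibroblasts its control ratio was 1.40, and the log2 value of 0.48 turned to -0.10 with every barcode and -0.04 at resolution 2.0. Over all cells, where the median gene lay at -0.45, the islet hormone genes ins (655 against 0.0935 CPM, 9.23) and sst1.1 (348 against 0.120 CPM, 8.28) and the acute phase gene crp2 (ENSDARG00000056498, a symbol shared by several identifiers; 1991 against 36.0 CPM, 5.75) were higher at 5 dpf. The inflammatory list had 12 of 23 members higher and 1 lower (median 0.64), and the unfolded protein response 15 of 24 lower (median -1.10, random range -0.62 to -0.12). As means of per-cell CPM ins was 8.34 and sst1.1 6.87.

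The log2 ratio of igfbp1a at 5 dpf minus that at 4 dpf was -2.40 in enterocytes and -1.29 in lysosome-rich enterocytes. These gaps were narrower in some alternatives: with called doublets kept the enterocyte ratios were 2.70 at 4 dpf and 1.78 at 5 dpf, and with 15 principal components those of lysosome-rich enterocytes were 1.47 and 0.90. They were wider in others: those of lysosome-rich enterocytes were 3.42 and 1.03 with a mitochondrial share of at most 10%, and 3.66 and 1.15 in cluster 16 alone. Across genes, which are not independent replicates, the log2 ratios of both days had a Pearson r of 0.32 and a Spearman rho of 0.31 over 10192 genes in enterocytes. In lysosome-rich enterocytes r was 0.28 and rho 0.31 over 11542 genes. The enterocyte ratios at 5 dpf compare classes of unlike cluster make-up, so the difference between days covers that change as well.

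Cells with at least 2 UMIs over 10 cell cycle genes, after thinning to 1000 UMIs, were 1.54% (0.881 to 2.48) of all cells with metronidazole and 2.79% (2.36 to 3.27) in control at 4 dpf. At 5 dpf they were 1.60% (1.33 to 1.91) and 2.27% (1.98 to 2.60). Among enterocytes such cells numbered 0 of 309 with metronidazole and 9 of 889 in control at 4 dpf, and 2 of 1687 and 1 of 2314 at 5 dpf. Among lysosome-rich enterocytes they numbered 4 of 246 and 25 of 1245 at 4 dpf, and 18 of 1417 and 5 of 1211 at 5 dpf. In the control library at 5 dpf 52 of the 109 T, NK and innate lymphoid cells (47.7%) met the rule, and with metronidazole 7 of 10. They were thus 52 of the 207 control cells and 7 of the 120 metronidazole cells that met it at 5 dpf. The difference over all cells at 5 dpf therefore covers the smaller number of lymphoid cells with metronidazole. These counts read transcripts alone, and free RNA in droplets was not removed.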

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

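The tests on the clusters of metronidazole cells at 5 dpf and the free RNA test on macrophages were chosen only after those results had been seen, and the other tests were planned before their results. Differences between the days were not tested, since each group held 1 library.

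Several metronidazole differences had opposite signs at 4 and 5 dpf. The cell cycle list in enterocytes had a median log2 ratio of -1.13 at 4 dpf and 0.36 at 5 dpf. Its summed level was 263 CPM at 4 dpf and 267 CPM at 5 dpf with metronidazole, and 496 and 205 CPM in control. The change of sign in that list therefore went with the control level, while the metronidazole level was nearly the same on both days. The brush border list in lysosome-rich enterocytes had 0.35 at 4 dpf and -0.50 at 5 dpf. The log2 ratio of the enterocyte share was 0.83 at 4 dpf and -0.12 at 5 dpf, but the value at 5 dpf was above 0 with every barcode (0.18), called doublets kept (0.0051), the Scrublet limit (0.032) and without liver, acinar and epidermal cells (0.022).

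Barcodes with over 25% mitochondrial UMIs, used only in the alternative with every barcode, also differed. They were 26.1% of the metronidazole barcodes against 21.4% in control at 4 dpf, and 21.7% against 17.8% at 5 dpf. Over their summed UMIs igfbp1a stood at 558 CPM (525 to 593) against 184 CPM (172 to 197) at 4 dpf and at 261 CPM (244 to 278) against 105 CPM (94.2 to 117) at 5 dpf.

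The first pattern weighed was the higher igfbp1a of both enterocyte classes with metronidazole. Free RNA was weighed from 1 named class at a time. It would give at most 0.529% of the excess in enterocytes and 4.60% in lysosome-rich enterocytes at 4 dpf. At 5 dpf it would give at most 20.8% and 1.24%, so each class tested was excluded as the main source. Classes with under 30 cells, hepatocytes among them at 4 dpf, were not tested. Goblet cells, unnamed cells and barcodes over the mitochondrial limit were not tested either, so free RNA from these sources stays open. Poorer RNA quality was weighed by mitochondrial share alone, and other measures of it were not tested. Among cells under 5% mitochondrial UMIs igfbp1a stayed higher in enterocytes on both days and in lysosome-rich enterocytes at 4 dpf. The lowest of these 3 log2 ratios was 1.66, so a higher mitochondrial share was not the main source there. The value of lysosome-rich enterocytes at 4 dpf, 2.895 (2.55 to 3.24), rested on 13 metronidazole and 134 control cells. At 5 dpf their log2 ratio among such cells was 0.69 (0.56 to 0.82), whose lower bound left the question open. A difference between library preparations cannot be told apart from the treatment with 1 library per group, and a response to metronidazole or to the loss of cells stays open beside it, untested.

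The second pattern was that single clusters held most metronidazole cells of both enterocyte classes at 5 dpf, with shares up to 55.6 percentage points above control in enterocytes and 61.1 in lysosome-rich enterocytes. The median depth of lysosome-rich enterocytes was not lower with metronidazole, at 1.08 times that of control. Its bootstrap interval of 1.02 to 1.14 resampled cells of 1 library per group. Thinning to 2000 UMIs nonetheless took the difference to 14.51 points. A lower resolution and the 10% mitochondrial limit also narrowed it, so thinning cannot decide whether depth shaped these clusters. Free RNA from liver and pancreas cannot be told apart from unstable clustering in lysosome-rich enterocytes. Without 507 such genes the difference was 15.14 points, and without as many random genes 58.7. It was also 13.5 at resolution 0.5 and 12.2 with the 10% mitochondrial limit. In enterocytes the difference was 7.003 with cells thinned and 2.47 without the liver and pancreas genes. Random genes also took it to 13.9, so depth and free RNA cannot be told apart there from unstable clustering. The pancreatic genes ela2, ctrl and cpa5 stood at 41.7, 34.4 and 34.0 CPM in metronidazole enterocytes. In control enterocytes they stood at 2.33, 2.405 and 2.68 CPM. Against a shift common to all cells of the library, smooth muscle differed by 5.10 points, but it stays open because fibroblasts differed by 17.4 points and the fullest endothelial cluster already held 85.1% of the control cells.

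The third pattern was enterocyte transcripts in metronidazole macrophages at 5 dpf, whose mean marker count was 6.80 times that of control macrophages. Free RNA in droplets enters every cell and was excluded as the main source, since the median macrophage had 1.07 times the control count. With cells thinned to 1000 UMIs the median ratio was 1, and 2 macrophages of 70 held at least 20 such UMIs against 0 of 67 in control, so a few doublets of a macrophage and an enterocyte are a candidate explanation. Such cells were 2.99% against 0.518% of endothelial cells and 1.82% against 0.189% of fibroblasts, so the pattern was not one of macrophages alone, but 1.71% against 1.39% of smooth muscle and 0 of the neutrophils (9 against 11) and lymphoid cells (10 against 109). Scrublet had removed 126 cells from the control library at 5 dpf and 0 from the metronidazole library. These shares therefore set a library with called doublets removed beside one in which no doublet was called. Uptake of enterocyte material by the 2 macrophages, which held 79.1% of the 4316 UMIs, stays open.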

How the results depend on the processing

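The Scrublet limit, the shares without liver, acinar and epidermal cells, the single clusters and the macrophages without immune cluster 6 were tests chosen after the results had been seen. Libraries can be matched by day, but with 1 library in each group no paired analysis was run. Of 2716 alternative values, 2680 had the sign of the value reported, 1916 lay within its interval and 780 lay past it. Another 20 reversed, which means the other sign for a value whose interval had excluded 0. The remaining changes of sign were in values whose interval held 0. Gene values carry 1 CPM added and their intervals do not, so a value of low CPM can lie outside its own interval. In enterocytes at the later day sqlea was 2.76, with an interval of 2.90 to 3.58. The counts within and past the interval are therefore not a measure of stability. Nor is the count of signs. Adding 10 CPM or lowering the UMI minimum cannot turn the sign of a gene ratio, and shares in percent have none to turn. For the reversals and shifts listed here the cause was not tested, except that 10 CPM added shrinks ratios by construction and thinning or a looser rule moves shares of cells with a UMI. The 4 dpf metronidazole library has the fewest cells, 1073. Clustered with a mitochondrial limit of 10%, 26 of them carried the enterocyte name (68 in control), too few for values of that class at 4 dpf. All values are log2 ratios unless a unit is given.

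The enterocyte share at 4 dpf, reported as 0.83, was 1.18 with the 10% limit, 1.07 with called doublets kept, 1.199 at resolution 2.0 and 1.03 with the Scrublet limit. At 5 dpf the share of -0.12 reversed to 0.18 with every barcode, 0.0051 with called doublets kept, 0.032 with the Scrublet limit and 0.022 without liver, acinar and epidermal cells. The lysosome-rich share at 5 dpf, 0.45, was 0.16 with the 10% limit, 0.86 with every barcode, 0.72 with 15 principal components and 0.59 without liver, acinar and epidermal cells. The enteroendocrine share of -2.42 was -1.16 with 15 principal components.

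In enterocytes at 4 dpf igfbp1a (4.01) was 2.88 with every barcode, 2.70 with doublets kept, 4.27 at resolution 2.0, 2.49 with the Scrublet limit, 4.27 as mean per-cell CPM and 3.50 with 10 CPM added. At 5 dpf (1.62) it was 1.78 with doublets kept, 1.40 at resolution 2.0, 1.42 with 15 principal components, 1.53 with median-ratio scaling, 1.47 as mean per-cell CPM, 1.39 with 10 CPM added and 1.51 in clusters 0 and 1. Between control days (0.73) it was 1.74 with the 10% limit, 0.26 with doublets kept, 1.15 at resolution 2.0, 0.61 with 15 principal components, 1.03 with median-ratio scaling, 1.26 as mean per-cell CPM and 0.53 with 10 CPM added.

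In lysosome-rich enterocytes at 4 dpf igfbp1a (2.39) was 3.42 with the 10% limit, 2.08 with every barcode, 1.47 with 15 principal components, 1.95 as mean per-cell CPM and 3.66 in cluster 16. At 5 dpf (1.099) it was 1.03, 0.86 and 0.90 under the first 3 of these, 1.04 at resolution 0.5 and 0.97 at resolution 2.0. In fibroblasts at 4 dpf (3.88) it was 3.74 with doublets kept and 4.08 at resolution 0.5. At 5 dpf in fibroblasts (0.23) it reversed to -0.29 with the 10% limit, -0.10 with every barcode, -0.091 with doublets kept and -0.23 at resolution 2.0. Between control days in fibroblasts (0.48) it reversed to -0.10 with every barcode and -0.043 at resolution 2.0, and in hepatocytes at 5 dpf (-0.08) to 0.24 as mean per-cell CPM.

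Of the lists, cell cycle in enterocytes at 4 dpf (-1.13) was -0.78 with doublets kept, -0.74 with the Scrublet limit and -0.37 with 10 CPM added, and at 5 dpf (0.36) it was 0.093 with 10 CPM added and 0.44 in clusters 0 and 1. Cholesterol synthesis in enterocytes at 4 dpf (0.50) was 1.02 with every barcode, 0.82 with doublets kept and 1.01 with the Scrublet limit, and at 5 dpf (1.27) it was 0.87 with 10 CPM added. Lipid absorption in lysosome-rich enterocytes at 5 dpf (-0.59) reversed to 0.29 with 15 principal components. In enterocytes at 4 dpf top2a and mki67 (-1.85 and -2.23) reversed to 0.31 and 0.90 with every barcode, 0.34 and 0.18 with doublets kept, and 0.27 and 0.29 with the Scrublet limit. In macrophages without immune cluster 6, ccl35.2 (-5.45) and arg2 (-3.75) reversed to 0.60 and 1.25.

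Cycling cells over all cells, in the order control 4 dpf, metronidazole 4 dpf, control 5 dpf and metronidazole 5 dpf, were 9.44%, 7.08%, 4.89% and 4.13% without thinning and 5.99%, 4.13%, 4.54% and 3.69% with a rule of at least 1 UMI. Enterocytes with igfbp1a were 1.35%, 23.0%, 2.55% and 6.76% after thinning. At least 1000 UMIs per cell kept 76.3% of control 4 dpf, 78.1% of control 5 dpf and 73.8% of metronidazole 5 dpf barcodes.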

Other observations

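The values given here were chosen after they had been seen, and none was tested.

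Between 18.1% and 22.9% of each library's cells had no class name. Among the leading genes of their larger clusters were slc12a10.1 and hoxb13a (1572 cells), malb and cldnh (884), podxl, jam2b and aqp1a.1 (599), cnfn, icn and tcnba (506), anxa4, stm and krt18a.1 (426), and the mural cell genes pdgfrb, notch3 and ebf1b (419). One small cluster led with top2a and mki67 and held 58 cells of control 4 dpf, 9 of metronidazole 4 dpf, 6 of control 5 dpf and 10 of metronidazole 5 dpf. Epidermal cells were 3.72%, 1.58%, 1.12% and 1.27% of the same libraries.

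The paralogue igfbp1b had levels unlike those of igfbp1a. In enterocytes it stood at 9.65 CPM in control and 24.4 CPM with metronidazole at 4 dpf, and at 25.01 and 28.4 CPM at 5 dpf. In lysosome-rich enterocytes it stood at 46.2 and 85.2 CPM at 4 dpf and at 141 and 134 CPM at 5 dpf. Hepatocytes at 5 dpf held 289 and 290 CPM.

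Transcripts of NfsB-EGFP were also counted in goblet cells, at 99.1 CPM in control and 58.2 CPM with metronidazole at 4 dpf and at 112 and 79.2 CPM at 5 dpf. In best4 cells they stood at 68.6, 66.4, 99.5 and 110 CPM and in lysosome-rich enterocytes at 72.0, 50.4, 61.0 and 55.8 CPM, in the same order.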
